A study of Homo sapiens with 15 samples.

How the data were processed

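RNA was measured by sequencing of mRNA libraries made with a SMARTER kit from 1.3 µg of RNA of 293T cells. Sample labels gave the groups and replicate numbers: fed cells, cells starved of serum for 12 h, and starved cells with a hairpin against SRSF1, with 3 libraries each. Of the 15 samples in the series, the 6 with SRPK1 or UPF1 knockdown have no column in the table used here, so the planned comparisons with them and between knockdowns were not run. The labels name 0 libraries with a non-targeting hairpin. Nothing in the labels says whether replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

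The deposited signal values are, in each of the 9 libraries, whole read counts per gene divided by 1 size factor per library, although the name of the deposited table calls them FPKM. In every library 100% of values were whole multiples of 1 step, to a relative tolerance of 1e-08, whatever the gene's length. The steps corresponded to size factors 0.709% to 1.50% below those recomputed as median ratios. Planning had assumed FPKM. Starved replicate 1 has a size factor so close to 1 that its reads were not taken as recovered, and the count-based test left it out. The aligner and the counting tool were not given in the sources used here. The processing notes name the mouse build mm10, but the gene identifiers are human: 19830 of 19849 identifiers found in GENCODE release 29 lay at an overlapping GRCh38 position, and 19812 were protein coding. Recovered totals were 11775367 to 15231651 reads per library; counting error alone is small at the median kept gene, which had a mean normalized count of 568.

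FPKM was computed from the values and the lengths in the table, and a gene was kept at 1 FPKM or more in at least 3 libraries. This kept 11133 of 19966 genes and left out 8833. Log2 values with a pseudocount of 1 were compared with limma (trend, 3 group means over all 9 libraries), with two-sided tests and Benjamini-Hochberg adjustment at 0.05 over all kept genes in each comparison. The comparisons of starved with fed cells and of knockdown with starved cells were fixed before the data were examined. Knockdown against fed cells was added after the data were seen. The overlap of the first 2 comparisons was set against 20 simulated data sets that share the starved libraries and against independent lists.

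In all, 30 gene lists were fixed before the data were examined, of which 26 had at least 5 kept members and were tested, and 13 list members had no entry in the table. Lists were compared with other genes by camera with a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. Some genes stand on several lists, such as ATF3, DDIT3, GADD45A and CDKN1A, so the list results are not independent. Named genes followed a rule fixed beforehand: the 8 largest changes each way among genes past the threshold, at 5 FPKM or more in the higher group and without overlap between groups, up to 4 members of each list with the largest changes past the threshold, and the targeted gene. SRPK1 and UPF1, markers of other cell types and genes named for the word ACACGTA stand outside it, and the last were chosen after their values were seen.

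A scan chosen after the data were seen scored each of 16382 words of 7 bases (of 16384 possible) in the longest coding transcript of 11112 genes, in 3 comparisons and 2 directions, against fold changes limited to 3 on the log2 scale and adjusted for transcript length and GC content. On data with a planted shift of -0.20 it placed the planted word first in 20 of 20 runs.

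The limma test was tested on simulated data with 200 changed genes in each of 5 runs. It recovered 16.4% and 20.0% of genes changed 1.25-fold (starved against fed, and knockdown against starved), 79.6% in both at 1.5-fold and 98.8% in both at 2-fold, with 4.30% and 5.58% of calls false. Camera called 20 of 20 lists shifted by 0.3 and 0 of 20 lists not shifted. These camera runs did not vary the correlation between genes of a list. In the real lists it was estimated at -0.04 (interferon response genes) to 0.73 (mitochondrially encoded mRNAs). The runs therefore do not show how often camera falsely calls a list whose genes are correlated.

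The settings varied were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median ratio, TPM and quantile scaling, limma without trend or with robust variance, only the 2 groups compared, a replicate block, a fold of 2 or more, and leaving out each library in turn. Removal of trends on GC content or gene length, leaving out mitochondrial genes, and edgeR's quasi-likelihood test on 8 libraries were chosen after seeing the data. DESeq2 was planned for raw counts alone and was not run. Work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.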

Results

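RNA sequencing was done on 293T cells, a human embryonic kidney line that carries the SV40 large T antigen, grown with serum or held without serum for 12 h. The series lists 15 samples in 5 groups of 3: fed cells, starved cells, and starved cells with a short hairpin RNA against SRSF1, SRPK1 or UPF1. The table used here has 9 libraries, 3 each of fed cells, starved cells and starved cells with the SRSF1 hairpin. The 6 samples with SRPK1 or UPF1 knockdown were not analysed here. SRSF1 is a splicing factor of the SR protein family, SRPK1 a kinase that phosphorylates SR proteins, and UPF1 the central helicase of nonsense-mediated mRNA decay. Libraries held between 11775367 and 15231651 reads in genes, and between 15166 and 15720 genes had at least 1 read. Of 19966 genes, 11133 passed the level filter and were tested.

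The 9 libraries separated by group. The first principal component held 54.9% of the variance and set the starved libraries apart from the other 6. The second component set fed cells apart from knockdown cells. Correlations of log2 values across genes were 0.967 to 0.994 within groups and 0.925 to 0.975 between groups. Mitochondrially encoded genes took 3.61 ± 0.33% of the normalized counts in fed cells, 3.95 ± 0.52% in starved cells and 4.28 ± 1.12% in knockdown cells (SD, n = 3 each). Knockdown replicate 3 stood apart from the other 2 knockdown libraries. Its correlations with them were 0.974 and 0.967, against 0.991 between those 2. It lay above 0 on the third component (12.6% of the variance), the other 2 at -9.27 and -20.7. Its mitochondrial share was 5.56% (95% Wilson interval 5.55 to 5.57%), against 3.52% (3.51 to 3.53%) and 3.75% (3.74 to 3.76%) in replicates 1 and 2, and these intervals cover counting error only. Starved replicate 2 stood apart by less, with correlations of 0.985 and 0.984 with the other 2 starved libraries against 0.992 between those, and -16.4 on the third component against 5.66 and 8.74. Its mitochondrial share was 4.54% (4.53 to 4.55%), against 3.61% (3.60 to 3.62%) in starved replicate 3 and 3.69% in starved replicate 1, whose reads were not recovered and which has no interval.

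**Figure D1:**
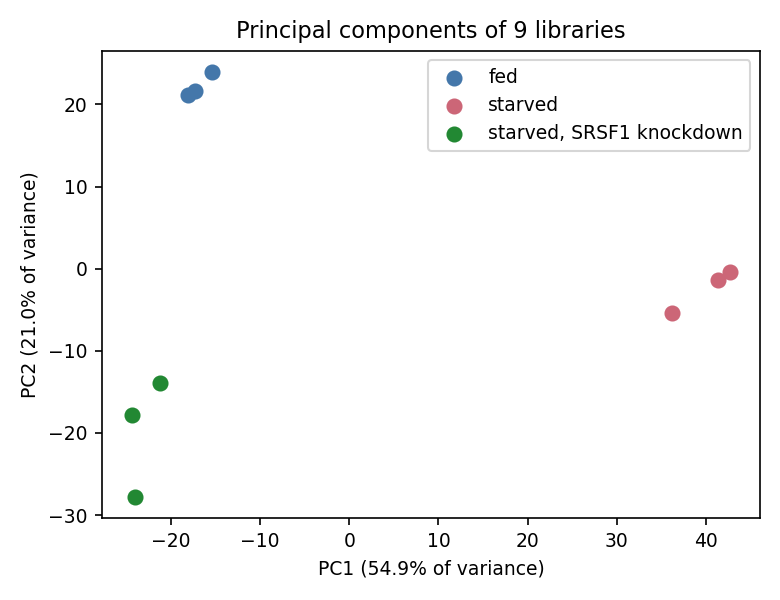
First and second principal components of log2 normalized counts over 11133 genes, 1 point per library, coloured by group. The starved libraries lie apart from the fed and knockdown libraries along the first component, which holds 54.9% of the variance.

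The knockdown label was first set against the level of its target. The SRSF1 gene (ENSG00000136450, chromosome 17, 58000919 to 58007346, GRCh38) stood at 2515 ± 63.5 normalized counts in fed cells, 3246 ± 85.4 in starved cells and 2409 ± 40.3 in starved cells with the hairpin (SD, n = 3 each). It rose on starvation by 0.37 ± 0.07 on the log2 scale (SE; limma adjusted p = 0.00231) and was lower in knockdown than in starved cells by 25.8% (log2 fold change -0.43 ± 0.07, limma adjusted p = 0.000797). All 3 knockdown libraries lay below all 3 starved libraries. Against fed cells the difference in SRSF1 was -0.06 ± 0.07 (limma adjusted p = 0.593) and did not pass the test. Most genes moved by starvation were also called the other way in the knockdown (below). The fall in SRSF1 cannot be told apart from that wider change. SRPK1, at 1886 ± 132 in knockdown and 2050 ± 191 in starved cells, and UPF1, at 3311 ± 242 and 3188 ± 297, did not pass the test between those groups.

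The first comparison asked what 12 h without serum did to the cells. Genes of sterol synthesis and uptake rose: 25 of 32 measured members were higher in starved cells and none was lower, among them IDI1 (log2 fold change 1.82 ± 0.09), HMGCS1 (1.58 ± 0.09) and INSIG1 (1.49 ± 0.08), with n = 3 in each group. Unfolded protein response genes rose in 17 of 21 cases and fell in 0, led by HERPUD1 (1.52 ± 0.09), MANF (1.40 ± 0.15) and DNAJB9 (1.35 ± 0.13). The HSP70 chaperone genes HSPA1A (2.36 ± 0.14) and HSPA1B (2.21 ± 0.10) rose, though these near-identical copies can share reads and their split is uncertain. Single genes with the largest rises were the galanin receptor gene GALR2 (ENSG00000182687, chromosome 17, 76074781 to 76077537, GRCh38), at 122 ± 6.87 normalized counts against 6.71 ± 0.50 (SD, n = 3; 16.0-fold), TMEM198 (7.24-fold), TMEM79 (6.31-fold), the decoy TRAIL receptor gene TNFRSF10D (6.16-fold), JOSD2 (5.18-fold) and SYP (4.87-fold). The largest falls were in the ephrin gene EFNB3 (log2 fold change -2.99 ± 0.20), SNAPIN (-2.68 ± 0.22), the ESCRT-III gene CHMP6 (-2.66 ± 0.17), the gamma-tubulin complex gene TUBGCP3 (-2.63 ± 0.14), the O-fucosyltransferase gene POFUT1 (-2.60 ± 0.09), the kinase gene NEK3 (-2.55 ± 0.12), PGBD1 (-2.52 ± 0.17) and the tafazzin gene, listed as TAZ (-2.48 ± 0.12). These 8 genes and the risers named with a fold had limma adjusted p from 5.49e-08 to 0.000356.

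In all, 4795 of 11133 genes changed between starved and fed cells (limma, Benjamini-Hochberg adjusted p under 0.05), 2396 higher and 2399 lower. Of these, 282 rose and 660 fell by a factor of 2 or more. The libraries of the 2 groups did not overlap for 59.3% of genes, where chance gives 10%. On a TPM scale, 1406 of 4133 called genes (34.0%) were higher and 2727 lower. With a filter of 5 FPKM, 1825 of 3115 (58.6%) were higher and 1290 lower.

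The sterol list (camera adjusted p = 5.79e-12) and the unfolded protein response list (5.90e-10) stood apart from other genes, and both calls held with an estimated correlation (adjusted p = 0.0187 and 0.0154). Adjusted over the list alone, 25 sterol genes and 18 unfolded protein response genes rose. Of 35 ATF4 and amino acid response genes, 19 rose and 4 fell over all genes, and 20 and 5 adjusted over the list alone; SLC7A11, which encodes the cystine transporter subunit xCT, rose by 1.45 ± 0.16, DDIT3 by 1.39 ± 0.27 and CTH by 1.31 ± 0.09 on the log2 scale. That list's camera call (adjusted p = 0.00124) was lost with an estimated correlation (adjusted p = 0.314). Ribosome biogenesis factors rose in 27 of 51 cases and fell in 4 (27 and 4 adjusted over the list alone), with UTP20 up by 0.94 ± 0.14 and WDR75 at -1.87 ± 0.10. Camera gave this list adjusted p = 0.00303, and adjusted p = 0.186 with an estimated correlation. Heat shock genes rose in 10 of 17 cases and fell in 3 (11 and 3 adjusted over the list alone), p53 targets rose in 13 of 27 and fell in 1 (14 and 1). Transcripts known as targets of nonsense-mediated decay rose in 12 of 17 and fell in 0 (12 and 0), with DDIT3, UPF2 (0.96 ± 0.17) and SMG1 (0.72 ± 0.16) among them. Camera gave these lists adjusted p = 0.00303, 0.0112 and 0.00262, and adjusted p = 0.186 for each with an estimated correlation. Autophagy and lysosome genes rose in 13 of 33 cases and fell in 3 (13 and 3 adjusted over the list alone). Camera gave adjusted p = 0.0207, adjusted p = 0.536 with an estimated correlation, and 0.0839 without starved replicate 2, within a range of 0.00481 to 0.536 over all settings tried for that list.

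The series title speaks of ribosomal stress, cell proliferation and MAPK signalling. Among 78 cytosolic ribosomal protein genes, 2 rose and 0 fell on starvation, RPL26 (0.47 ± 0.17) and RPS23 (0.26 ± 0.08), and 0 passed adjusted over the list alone. Reads of ribosomal protein genes can be shared with processed pseudogenes, and neither call held without fed replicate 1 (limma adjusted p = 0.0837 and 0.110), fed replicate 2 (0.128 and 0.0973) or starved replicate 1 (0.152 and 0.0940). RPL26 also lost its call without fed replicate 3 (0.0723) and RPS23 without starved replicate 3 (0.0589). Of 40 replication genes 4 rose and 6 fell (3 and 6 adjusted over the list alone), and of 38 mitosis genes 2 rose and 6 fell (2 and 5), with NEK2 at -1.02 ± 0.09 and CENPF at -0.94 ± 0.21. Of 60 MAPK pathway components 10 rose and 14 fell (10 and 14), with falls in EGFR (-1.65 ± 0.18) and FGFR1 (-1.13 ± 0.12). The ribosomal protein, replication, mitosis and MAPK component lists did not pass camera (adjusted p = 0.455, 0.968, 0.287 and 0.982).

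**Figure D2:**
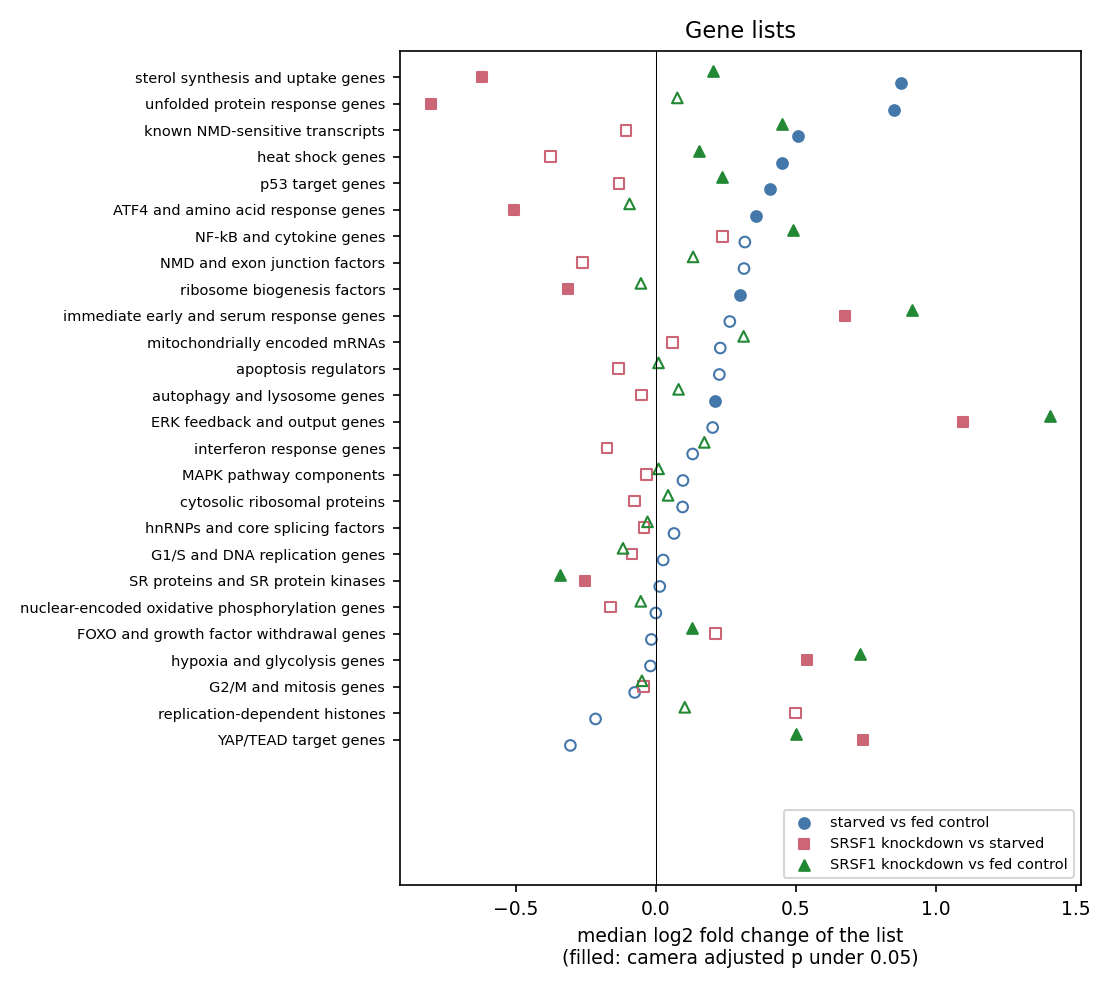
Median log2 fold change of each gene list (y axis) in the 3 comparisons (circles, squares and triangles); filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. The sterol and unfolded protein response lists lie at 0.88 and 0.85 in starved against fed cells and at -0.62 and -0.80 in knockdown against starved cells.

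The second comparison set SRSF1 knockdown against starved cells, both without serum. Immediate early and serum response genes were higher in the knockdown in 16 of 27 cases and lower in 2, led by the transcription factor genes EGR1 (ENSG00000120738; log2 fold change 4.09 ± 0.46), FOS (2.56 ± 0.38), FOSB (2.21 ± 0.29) and ATF3 (2.05 ± 0.12). ERK feedback and output genes rose in 12 of 15 cases and fell in 2, with ETV4 at 3.88 ± 0.38, ETV5 at 3.44 ± 0.33 and the ERK pathway inhibitor gene SPRED2 at 2.22 ± 0.14. Hypoxia and glycolysis genes rose in 24 of 31 cases and fell in 2, among them NDRG1 (2.73 ± 0.12), the glucose transporter gene SLC2A3 (2.39 ± 0.14), ENO2 (2.04 ± 0.10) and PGK1 (1.80 ± 0.10). YAP/TEAD targets rose in 14 of 17 cases and fell in 0, led by ANKRD1 (5.02 ± 0.47), NUAK2 (2.12 ± 0.27) and CCN1 (1.65 ± 0.17). Unfolded protein response genes fell in 18 of 21 cases, with DNAJB9 at -1.86 ± 0.13 and CRELD2 at -1.67 ± 0.13, and sterol genes fell in 24 of 32, with STARD4 at -1.53 ± 0.18 and IDI1 at -1.43 ± 0.09.

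Single genes with the largest rises were HBB, HSPA6, ARC, BHLHE40, MMP15 and GEM beside EGR1 and ANKRD1. HBB, the beta-globin gene (chromosome 11, 5225464 to 5229395, GRCh38), stood at 852 ± 21.5 normalized counts in the knockdown (SD, n = 3) and had 0 reads in the 3 starved libraries and 1 read in the 3 fed libraries. Set against a floor of 3 reads over the starved group, HBB was at least 786-fold higher. The other globin genes did not rise with it: HBD, HBG1, HBG2 and HBE1 had 0 reads in every library, HBA2 at most 1 and HBA1 at most 6. Whether the HBB reads come from the gene itself was not tested. HSPA6, a heat-inducible HSP70 gene, was 31.1-fold higher, the neuronal early gene ARC 11.1-fold, the transcription factor gene BHLHE40 8.71-fold, the metalloproteinase gene MMP15 7.74-fold and the GTPase gene GEM 7.30-fold. The largest falls were in SLC7A11 (-2.97 ± 0.16, 385 ± 36.1 against 3066 ± 722 normalized counts), GALR2 (-2.84 ± 0.25), JOSD2 (-2.39 ± 0.36), the thioredoxin reductase gene TXNRD1 (-2.20 ± 0.09), C11orf54 (-2.08 ± 0.13), the glutathione-degrading enzyme gene CHAC1 (-2.05 ± 0.20), C2orf76 (-2.04 ± 0.19) and TMEM198 (-1.98 ± 0.21). Limma adjusted p for these largest rises and falls ran from 8.88e-08 to 0.000308.

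**Figure D3:**
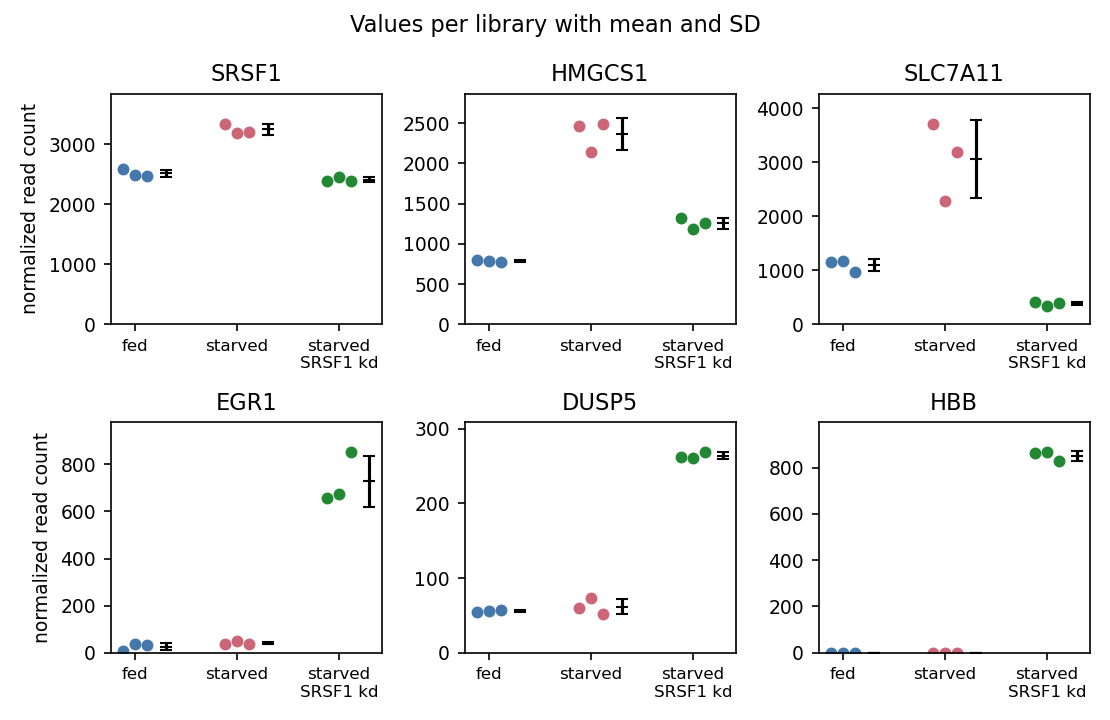
Normalized read counts of SRSF1, HMGCS1, SLC7A11, EGR1, DUSP5 and HBB in each library (points) with the group mean and SD (black, n = 3), on linear axes from 0. HBB lies at 852 ± 21.5 in the knockdown libraries and near 0 in the others.

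In total 5198 genes differed between knockdown and starved cells (limma, Benjamini-Hochberg adjusted p under 0.05), 2516 higher and 2682 lower, with 668 higher and 331 lower by a factor of 2 or more. The 2 groups' libraries did not overlap for 51.0% of genes, where chance gives 10%. On a TPM scale, 2637 of 4530 called genes (58.2%) were higher and 1893 lower, and with a filter of 5 FPKM 1426 of 3430 (41.6%) were higher and 2004 lower. Without knockdown replicate 3 the count was 5618. Fold changes rose with the GC content of the transcript (Spearman 0.21 across genes, which are not independent replicates).

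With camera, the calls on hypoxia and glycolysis (adjusted p = 9.85e-09), ERK output (1.11e-05), YAP/TEAD (2.99e-06) and immediate early genes (4.30e-05) were lost with an estimated correlation (adjusted p = 0.126, 0.0781, 0.0781 and 0.0781). The unfolded protein response and sterol calls (both adjusted p = 9.85e-09) held with an estimated correlation (adjusted p = 0.0223 and 0.0475). Counts adjusted over the list alone were 25 up and 2 down for hypoxia and glycolysis, 12 and 2 for ERK output, 14 and 0 for YAP/TEAD, 18 and 3 for immediate early, 0 and 20 for unfolded protein response, and 1 and 24 for sterol genes. ATF4 and amino acid response genes fell in 22 of 35 cases and rose in 6 (23 and 6 adjusted over the list alone), with ASNS at -1.41 ± 0.17 and GDF15 up by 1.61 ± 0.44. Camera gave the ATF4 list adjusted p = 0.000137, and adjusted p = 0.283 with an estimated correlation. Ribosome biogenesis factors fell in 27 of 51 cases and rose in 4 (27 and 4 adjusted over the list alone), with RPF2 at -1.03 ± 0.09 and WDR75 up by 1.58 ± 0.10. Camera gave biogenesis factors adjusted p = 0.000480, and adjusted p = 0.126 with an estimated correlation. SR proteins and their kinases fell in 10 of 21 cases and rose in 2 (10 and 2 adjusted over the list alone), with SRSF6 at -1.25 ± 0.10 and SRSF8 at -0.73 ± 0.11. The list includes SRSF1, and its camera call (adjusted p = 0.0361) was lost with an estimated correlation (adjusted p = 0.470), without starved replicate 1 (0.0670) and without knockdown replicate 2 (0.0617). Over all settings tried for that list the adjusted p ran from 0.00690 to 0.470. Of 60 MAPK components 20 rose and 15 fell (21 and 16 adjusted over the list alone), with DUSP10 (1.70 ± 0.24), EGFR (1.69 ± 0.18) and FGFR1 (1.53 ± 0.12) higher. Of 40 replication genes 6 rose and 9 fell (6 and 9), and of 38 mitosis genes 5 rose and 3 fell (3 and 1). Neither these 3 lists nor the ribosomal protein genes, 2 up and 6 down of 78 (1 and 3), passed camera.

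Genes that starvation moved were mostly called the other way in the knockdown. Of the 4795 genes called in starved against fed cells, 3296 (68.7%) were called in the opposite direction in knockdown against starved cells and 66 in the same direction. The 3296 comprised 1537 genes higher on starvation and lower in the knockdown, such as HMGCS1, HERPUD1 and GALR2, and 1759 lower and then higher, such as EGFR and WDR75. Against fed cells, 2846 of the 3296 (86.3%) did not pass the test in the knockdown, 6.10% still differed from fed cells in the direction of starvation, and 249 (7.55%) differed in the direction opposite to starvation. Among all 11133 tested genes, 18.9% passed that test, so not passing was common whatever the gene. Not passing does not show equal levels. The starved libraries enter both comparisons with opposite sign, which by itself favours opposite calls. In 20 simulated data sets with an unchanged knockdown group, opposite calls numbered 0 or 1. With no true change between knockdown and starved cells few genes could be called there, so this count says little about the shared libraries. Independent lists of these sizes would share 577 genes up and then down and 542 down and then up. The covariance of the 2 sets of log2 fold changes was -0.28 across genes (correlation -0.78), against -0.02 to -0.01 in the simulations. By the error of the starved mean, random spread of the shared libraries gives a covariance of -0.02, a small part of that seen. The share of the opposite calls that comes from this spread was not measured. The 3 starved libraries are too few to give each comparison 2 of its own. A shift common to all starved libraries may also add to the pattern.

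**Figure D4:**
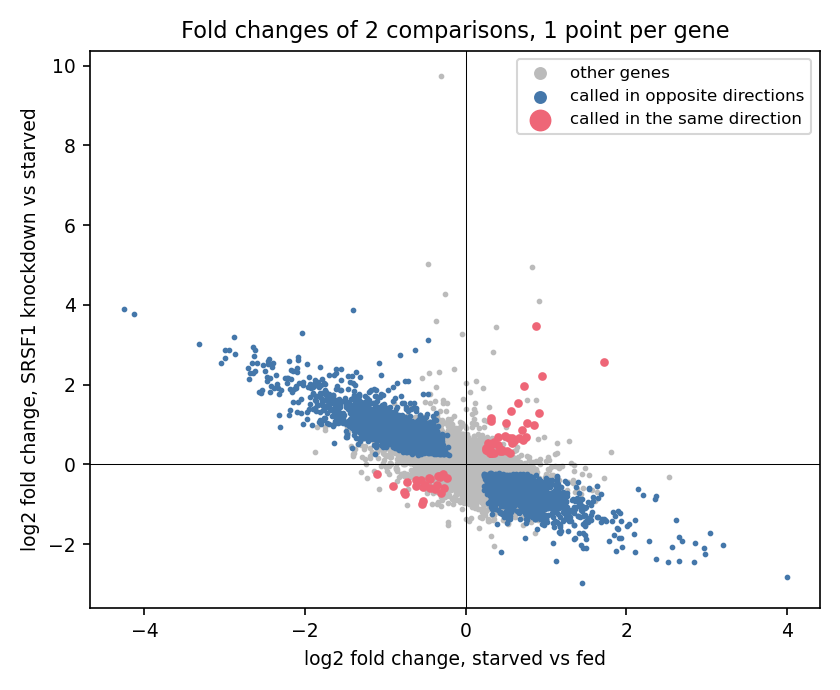
Log2 fold change in starved against fed cells (x axis) and in SRSF1 knockdown against starved cells (y axis), 1 point per tested gene. The 3296 genes called in opposite directions (blue) run from upper left to lower right, and 66 genes were called in the same direction (red).

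Knockdown was also set against fed cells, a comparison added after the data were seen. Early genes stood above fed cells as well: 18 of 27 immediate early and serum response genes were higher and 0 lower, led by EGR1 (5.01 ± 0.46), FOS (4.28 ± 0.38), FOSB (3.16 ± 0.29) and JUNB (2.21 ± 0.20). ERK output genes were higher in 11 of 15 cases and lower in 0, with ETV5 at 3.81 ± 0.33 and the ERK phosphatase gene DUSP5 at 2.22 ± 0.16, and the MAPK phosphatase genes DUSP8 (1.91 ± 0.15) and DUSP1 (1.55 ± 0.11) were higher too. Of the 38 genes on the early or ERK output list, 23 were higher in the knockdown than in both other groups. Hypoxia and glycolysis genes were higher in 24 of 31 cases and lower in 0, with NDRG1 at 1.91 ± 0.12 and PGK1 at 1.86 ± 0.10. Lower than in fed cells were TXNRD1 (-1.76 ± 0.09), the kinesin gene CENPE (-1.74 ± 0.33), CHAC1 (-1.70 ± 0.20), the amyloid precursor gene APP (-1.67 ± 0.09), GAMT (-1.57 ± 0.21), SLC7A11 (-1.51 ± 0.16), ID2 (-1.51 ± 0.09) and HMGN5 (-1.47 ± 0.12), with limma adjusted p from 1.56e-06 to 0.00493.

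Beside HBB, EGR1 and ANKRD1 (4.55 ± 0.47), the largest rises against fed cells were in HSPA6 (55.0-fold), ARC (log2 fold change 4.35 ± 0.27), BHLHE40 (6.27-fold), KRTAP19-1 (5.59-fold) and GEM (4.71-fold). Knockdown and fed cells differed in 2106 genes (limma, Benjamini-Hochberg adjusted p under 0.05), 1050 higher and 1056 lower, of which 109 and 85 by a factor of 2 or more; non-overlap held for 41.2% of genes, where chance gives 10%. The count was 840, 1024 and 1108 without fed replicate 1, 2 and 3, and 1625, 1643 and 2559 without knockdown replicate 1, 2 and 3. The reference transcripts of TXNRD1, CENPE, GAMT, C2orf76, DNAJB9, SRSF8 and BHLHE40, the last of which was higher, hold the 7-base word ACACGTA, picked after the data were seen, which occurs in 5.06% of tested genes and in 15.2% of the 1055 searched genes that were lower than in fed cells.

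The immediate early (camera adjusted p = 4.80e-13) and ERK output calls (4.37e-10) held with an estimated correlation (adjusted p = 0.0304 and 0.0419), and the hypoxia and glycolysis call (1.03e-17) was lost with an estimated correlation (adjusted p = 0.0641). Adjusted over the list alone, 18 immediate early genes, 12 ERK output genes and 27 hypoxia genes were higher, and 0, 0 and 1 lower. YAP/TEAD targets were higher in 10 of 17 cases and lower in 0 (10 and 1 adjusted over the list alone; camera adjusted p = 1.68e-06), known decay targets in 9 of 17 and 0 (9 and 0; 7.43e-06) and NF-kB genes in 4 of 8 and 0 (5 and 1; 0.00322), with RELB at 2.11 ± 0.19. Each of the 3 gave adjusted p = 0.0675 with an estimated correlation. The decay list shares GADD45A and CDKN1A with the p53 list and ATF3 with the immediate early list, so these list results are not separate. Sterol genes were higher in 11 of 32 cases and lower in 2 (13 and 2 adjusted over the list alone), with INSIG1 at 1.40 ± 0.08. Their camera call (adjusted p = 0.000402) was lost with an estimated correlation (adjusted p = 0.0893). Targets of p53 were higher in 8 of 27 cases and lower in 0 (9 and 2), with GADD45A at 1.57 ± 0.13 and CDKN1A at 1.35 ± 0.13, and the p53 call (camera adjusted p = 0.00506) was lost with an estimated correlation (adjusted p = 0.0893). Heat shock genes were higher in 6 of 17 cases and lower in 0 (6 and 1), and that call (camera adjusted p = 0.00395) was lost with an estimated correlation (adjusted p = 0.0893). FOXO and growth factor withdrawal genes were higher in 8 of 27 cases and lower in 2 (8 and 3). The FOXO call (camera adjusted p = 0.0348) was lost with an estimated correlation (adjusted p = 0.0893) and also without fed replicate 3 (0.0569), knockdown replicate 1 (0.0505) or knockdown replicate 3 (0.0637), within a range of 0.0182 to 0.285 over the settings tried. SR proteins and kinases were lower in 8 of 21 cases and higher in 1 (10 and 1 adjusted over the list alone), with SRSF6 at -0.91 ± 0.10 and SRSF8 at -0.83 ± 0.11. Camera gave adjusted p = 0.00589, and adjusted p = 0.337 with an estimated correlation. Unfolded protein response genes, 2 higher and 4 lower of 21 (7 and 5 adjusted over the list alone), ribosome biogenesis factors, 3 and 6 of 51 (3 and 5), and ribosomal protein genes, 0 and 1 of 78 (0 and 0), did not pass camera against fed cells.

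The remaining list results of the 2 planned comparisons did not pass camera. Factors of nonsense-mediated decay and the exon junction complex rose in 10 of 20 cases and fell in 3 on starvation (10 and 3 adjusted over the list alone; camera adjusted p = 0.0556), with DHX34 at 0.83 ± 0.10, and in the knockdown 2 rose and 9 fell against starved cells (2 and 9; 0.238), with UPF2 at -1.37 ± 0.17. In the same 2 comparisons the interferon list gave 7 up and 2 down, then 4 up and 7 down of 18 (7 and 2, then 5 and 8 adjusted over the list alone). Regulators of apoptosis gave 10 up and 5 down, then 5 up and 9 down of 28 (the same counts adjusted over the list alone). The hnRNP and core splicing factor list gave 5 up and 3 down, then 3 up and 6 down of 41 (2 and 2, then 2 and 6). Nuclear-encoded oxidative phosphorylation genes gave 3 up and 1 down, then 0 up and 6 down of 39 (1 and 0, then 0 and 1), mitochondrially encoded mRNAs 0 and 0, then 1 and 1 of 13 (0 and 0 both times), and replication-dependent histones 0 and 2, then 2 and 0 of 14 (0 and 1, then 0 and 0). On starvation YAP/TEAD targets rose in 1 case and fell in 8 of 17, with NUAK2 at -1.55 ± 0.27 (1 and 8 adjusted over the list alone; camera adjusted p = 0.220). In knockdown against starved cells heat shock genes rose in 2 and fell in 9 of 17 cases (2 and 11 adjusted over the list alone; camera adjusted p = 0.0860). In that comparison known decay targets rose in 6 and fell in 6 of 17 cases (6 and 6; median -0.11; camera adjusted p = 0.600), p53 targets in 8 and 7 of 27 (8 and 8; 0.850), autophagy and lysosome genes in 5 and 10 of 33 (5 and 10; 0.351), and NF-kB genes in 2 and 1 of 8 (2 and 1; 0.590). FOXO and growth factor withdrawal genes rose in 8 and fell in 7 of 27 cases on starvation (9 and 7; camera adjusted p = 0.627), and gave 11 and 5 in knockdown against starved cells (11 and 5; 0.466). On starvation SR proteins and kinases rose in 5 and fell in 1 of 21 cases (5 and 1; camera adjusted p = 0.695). On starvation immediate early genes rose in 9 and fell in 3 of 27 cases, ERK output genes in 3 and 5 of 15, hypoxia and glycolysis genes in 6 and 7 of 31, and NF-kB genes in 4 and 0 of 8, with the same counts adjusted over the list alone, and none of these lists passed camera (adjusted p = 0.166, 0.979, 0.753 and 0.0833). Every list that passed camera had its median, mean and test direction of 1 sign. MAPK components did not pass, and their median and mean had opposite signs on starvation (0.10 and -0.04) and in knockdown against starved cells (-0.03 and 0.10).

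Few markers of other cell types passed the level filter. Of the fixed marker lists, 3 fibroblast, 3 leukocyte, 4 carcinoma-line epithelial and 0 hepatocyte genes did, too few for a list test. Mean FPKM of the fibroblast genes in fed, starved and knockdown cells was 3.67, 1.73 and 3.32 for COL1A1, 1.28, 0.566 and 0.421 for LUM, and 1.12, 0.941 and 2.09 for S100A4. Of the leukocyte genes, CD14 stood at 0.436, 0.866 and 1.58 and CORO1A at 1.55, 0.656 and 1.85. Of the epithelial genes, KRT17 stood at 0.217, 0.239 and 2.11, KRT8 at 16.0, 7.51 and 18.4, KRT18 at 12.7, 11.5 and 14.1, and CDH1 at 1.78 in fed and 1.02 in knockdown cells, with a log2 fold change of -0.43 on starvation. Against fed cells the knockdown differed in KRT17 (log2 fold change 3.22), CD14 (1.65), LUM (-1.56) and CDH1 (-0.77).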

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

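The test of residual serum below, and the margin of 1 standard error asked of the sterol median, were chosen only after the result was seen. The serum test takes every tested gene of the early and ERK output lists and rests on the values that form the pattern, so the sign of its median was known before it ran. A first version on early genes picked for being higher than in starved cells was void and was dropped. Each comparison of 3 with 3 libraries allows 10 splits of the 6 libraries, too few for a share under 0.05. In fits of the 2 groups alone, only the real split, 1 of the 10, gave as many genes as the 5664 in starved against fed cells, and the highest of the other splits gave 0. The same held for knockdown against starved cells (1 of 10, with 4225 genes and 0 at the highest other split) and for knockdown against fed cells (1 of 10, with 1915 and 0).

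Of the 4795 genes that differed on starvation, 3296 were called the opposite way in the knockdown, and 2846 of these did not pass against fed cells. Among all tested genes, 18.9% passed against fed cells. Random spread of the starved libraries shared by both comparisons is argued against as the whole cause, since the covariance of the fold changes was 17.1 times that given by the error of the starved mean. That error holds only the spread between libraries of a group. A shift common to all starved libraries would give the same pattern and was not tested. Removing a trend on GC content kept 94.7% of the 3296 genes, removing a trend on length kept 97.6%, and leaving out any 1 starved library kept at least 76.8%. It stays open whether the knockdown cells were starved to the same degree. Their sterol list lay above fed cells by a median of 0.20 ± 0.08 (log2, SE of the median), with camera adjusted p = 0.000402. This met the rule set before the test, a median of 0.2 or more with a camera adjusted p under 0.05. It did not meet the margin of 1 standard error asked afterwards, so knockdown cells that were not starved are not excluded. An effect of SRSF1 loss on the response to starvation may be at work too, but with no non-targeting hairpin it cannot be separated from an effect of carrying a hairpin. SRSF1 itself rose by 29.1% on starvation and lay 4.19% below fed cells in the knockdown. Its fall from the starved level may thus be part of the same opposite change.

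Of 38 immediate early and ERK output genes, 23 stood higher in the knockdown than in both other groups. Residual serum as the whole cause would leave genes that follow the serum dose between starved and fed levels. Over all 38, changed or not, the knockdown lay above the higher of the other 2 groups by a median of 0.69 ± 0.22 (log2), with 28 above both. This SE of the median is taken over genes, not libraries. On starvation 14 of the 38 were lower, and whether these genes follow the serum dose was not tested. The values therefore argue against residual serum only for genes whose level moves steadily with serum. Leaving out any 1 knockdown library kept at least 91.3% of the 23 genes. An interferon response to the hairpin stays open: the interferon list had a median of 0.17 against fed cells (quartiles -0.14 and 0.46), with 4 of 18 members higher and 0 lower (camera adjusted p = 0.260), and of -0.17 against starved cells (quartiles -0.59 and 0.35), with 4 higher and 7 lower (camera adjusted p = 0.889). Handling of the dishes just before harvest, which may raise early genes, and loss of SRSF1 itself were not tested apart.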

How the results depend on the processing

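The comparison of knockdown with fed cells, removal of GC and length trends, leaving out mitochondrial genes, edgeR, and leaving out libraries for the early and ERK output genes were chosen only after the data were seen. Asking for a fold of 2 or more left 942 genes in starved against fed cells, 999 in knockdown against starved cells and 194 in knockdown against fed cells, as a stricter threshold must. A filter of 5 FPKM tested 7417 genes and left 3115 and 3430 genes in the first 2 comparisons, 2100 genes called in opposite directions and 14 early and ERK output genes above both other groups, with fewer genes tested. Leaving out 1 library in turn gave 3687 to 4660 genes in starved against fed cells, 4114 to 5618 in knockdown against starved cells, 2585 to 3841 called in opposite directions and 19 to 24 early and ERK output genes. For knockdown against fed cells it gave 840 to 2559, with 840, 1024 and 1108 without fed replicate 1, 2 and 3, and the cause was not tested. SRSF1 was called lower than in starved cells in every setting run, by -0.44 to -0.29 on the log2 scale, with -0.29 after removal of the GC trend. Because SRSF1 also rose on starvation, these calls do not separate a knockdown from the wider opposite change.

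The replicate numbers did not pair the libraries throughout: residuals of 9 same-numbered pairs correlated by -0.46 to 0.54, with 3 pairs over 0.1. Between starved and knockdown libraries same-numbered pairs gave 0.07, 0.54 and 0.30, and other pairs -0.38 to 0.18. Same-numbered pairs with a fed library gave -0.46 to 0.26. Whether starved and knockdown libraries were paired stays open. Some differently numbered libraries were also correlated, such as fed replicate 3 with starved replicate 2 (0.54). With the numbers as a replicate block, 4887, 5260 and 2172 genes changed in the 3 comparisons, 3343 in opposite directions. On 8 libraries edgeR called 3880, 4083 and 1932 genes. Over 310 results on named genes, 6177 repeats counted as unchanged, 268 lost the call and 0 reversed. A repeat counted as unchanged, whatever its direction, where neither fit passed. Most named genes were picked for large changes in these same libraries, which favours repeats that hold. Over 28 list calls, 549 repeats kept the call, 39 lost it, 22 of these with an estimated correlation, and 0 reversed. Depth was not varied. With the depth and number of libraries at hand, 16.4% of the smallest simulated changes were found in starved against fed cells. That simulation changed 200 genes, far fewer than the 4795 called, so its recovery need not hold for these data. DESeq2, and every alternative on SRPK1 or UPF1 knockdown, was not run.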

Other observations

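All tests in this part were chosen only after the data were seen. Among 16382 words of 7 bases, ACACGTA had the lowest score in knockdown against fed cells (-13.4) and in knockdown against starved cells (-9.76). In starved against fed cells its score was 1.41. The next words against fed cells were CACGTAA (-10.5), CACGTAT (-8.80) and GCACGTA (-7.62). All of them share the bases CACGTA with ACACGTA, so their scores are not separate from its score. The 562 genes with the word in a reference transcript were lower than the others by a mean log2 difference of -0.22 ± 0.02 against fed cells (SE), and each knockdown library showed it (-0.28, -0.29 and -0.30 for genes with the word in the 3 prime UTR alone). Of 304 genes with the word in the 3 prime UTR alone, 104 (34.2%) were lower than in fed cells, against 8.52% of 10447 genes without it. The 8 genes with 2 or more sites in the 3 prime UTR differed from those without the word by -0.23 ± 0.18 (SE). The 30 genes with the word in the 5 prime UTR alone differed by 0.09 ± 0.11.

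A chance choice among so many words is argued against by putting alternate genes into separate parts: the word lowest in either part was ACACGTA, with a score of -9.33 or lower in the other part. A DNA sequence read on both strands is argued against by the reverse complement, whose shift was 12.4% of that of the word. Genes with the word in coding sequence alone were also shifted lower against fed cells than genes without it (-0.17 ± 0.03, with 21.3% of 216 called lower), and the shift with the word in the 3 prime UTR alone exceeded theirs by -0.12 ± 0.04 against fed cells and by -0.08 ± 0.05 against starved cells, the latter under 2 SE. A short RNA pairing with 3 prime UTRs therefore stays open, as does whether it could come from the hairpin, whose sequence is not given in the sources used here. In SRSF1 the word lies in an intron kept in 2 of 9 reference transcripts (chromosome 17, 58005785 to 58005791, GRCh38). It is annotated as coding sequence in both, and 1 of the 2 is listed as protein coding. At the gene's 3 prime end, 2441 bases were not searched.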
